A study of Mus musculus with 9 samples.

How the data were processed

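Total RNA of mouse liver, 8 µg per sample from frozen 100 mg aliquots, was labelled with biotin and hybridised to Affymetrix arrays with a single colour, per the labels' protocols. The deposited value table holds 1 intensity per probe set and array on a linear scale for 9 arrays. The software, background correction and scaling used by the authors are not given in the sources used here. In the deposited intensity values the mean after trimming 2% at each end was close to 500 on every array (500.003 to 500.005), so each array had been scaled to a common level. The table carries no detection calls, so no probe set could be called above or below background.

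Array columns were matched to samples by their names, and groups were taken from the labels: 5 BKS and 4 db/db. No pair of arrays held identical values. The intensities were transformed as log2(value + 16). The medians of the arrays then spanned 0.60 on the log2 scale, above the limit of 0.25 set for this step, so the arrays were quantile normalized with limma 3.58.1 in R 4.3.3. The pseudocount of 16 compresses the fold changes of dim genes.

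Of the probe sets, 34945 had 1 gene symbol, 932 had several, 9160 were not listed in the annotation used and 64 were controls. For 34754 of those with 1 symbol the gene identifier matched the RefSeq gene table, and no symbol needed to be changed. Probe sets with several symbols or none were left out of the gene table. Each gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes, with no filter on dim genes. Genes for which no probe set carried the symbol alone were not analysed here.

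Each gene was tested with limma (lmFit and eBayes with an intensity trend, two-sided, group as the only term) and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. "Rose" and "fell" refer to genes past that threshold. Gene lists drawn from textbook knowledge were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over 43 lists. Of 775 listed genes 697 were measured. Some lists share genes. Fry tests whether the genes of a list move, on balance, in 1 direction, and camera whether they move more than other genes.

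The limit for normalization, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule named Lepr, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, and from each list the members with the smallest adjusted p in each direction, up to 2 per direction (4 for the lists of peroxins, peroxisomal and mitochondrial fatty acid oxidation and oxidative phosphorylation). Predicted genes would have been passed over among the largest changes, and none had to be.

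The table of control probe sets showed that the arrays fall into 2 sets by the signal for 18S ribosomal RNA, split at the largest gap in that signal. The labels give no batch. This split was found after the data were seen. It was added to the fit as a block, and each set of arrays was also analysed alone.

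The labels number the samples within both groups. Whether equal numbers pair samples was checked from the correlation of their deviations from the group means, and the numbers were not taken as pairs.

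The steps were tested on simulated data made from the real probe set means, the 18S split and the residual spread, with 200 changed genes drawn anew from the brighter probe sets in each of 20 rounds over 18193 genes. For this comparison the test recovered 11.0% of genes changed by 1.5-fold, 39.0% of those changed by 2-fold and 82.6% of those changed by 4-fold. At 4-fold the recovery ran from 71.2% to 89.4% over rounds. Of 1785 calls 25 were false (1.40%). With the block the recovery was 21.0%, 52.3% and 88.0%, and 86 of 2229 calls were false (3.86%). Changes of 2-fold or less are therefore often missed with this number of arrays. Of 200 lists of unchanged genes 3 had a camera p under 0.05, with and without the block. Apart from the 18S split the simulated genes varied independently. This result therefore does not check camera at the preset correlation on real lists whose genes vary together (estimated correlation up to 0.50, for male-biased genes).

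Alternatives changed 1 choice at a time: centring on the median, other pseudocounts, filters on dim genes, other probe set rules, eBayes without a trend or robust, array weights, Welch's test per gene, the replicate number as a block, each array left out in turn, and other list tests. The probe set of a gene was picked anew in each fit. For some genes another scaling, pseudocount or set of arrays therefore also changed the probe set. Values without quantile normalization, the 18S block, each 18S set alone and the block with averaged probe sets were added after the data were seen. Real groups were also set against 100 splits of the 9 arrays, the real one included, drawn with a fixed seed. Single scores per array were compared with exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.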

Results

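RNA levels were measured in liver of male mice at 14 weeks of age. The db/db mouse carries a mutation of the leptin receptor gene and becomes obese and diabetic with a fatty liver, per the study's design. BKS mice of the same background, littermates with the intact receptor gene, were the controls. There were 5 BKS and 4 db/db samples, each on its own array with a single colour, and 18193 genes could be named and tested. The median signal of an array lay between 67.4 and 110.8, and correlations between arrays over genes lay between 0.919 and 0.967. The number of arrays limits the precision. The labels number the samples without saying that each came from a different mouse, so the p-values measure the spread between these samples.

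The arrays differed by genotype and by a technical property. The first principal component held 24.5% of the variance and separated the genotypes. The second held 19.3%, and 88.2% of it went with the signal of control probe sets for 18S ribosomal RNA. That signal was 1873 to 19771 on BKS 4, BKS 5, db/db 3 and db/db 4, and 22.2 to 43.5 on the other 5 arrays. Both sets of arrays hold both genotypes, so values are also given with this split as a block and, as differences of group means of the values normalized over all 9 arrays, within each set.

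**Figure D1:**
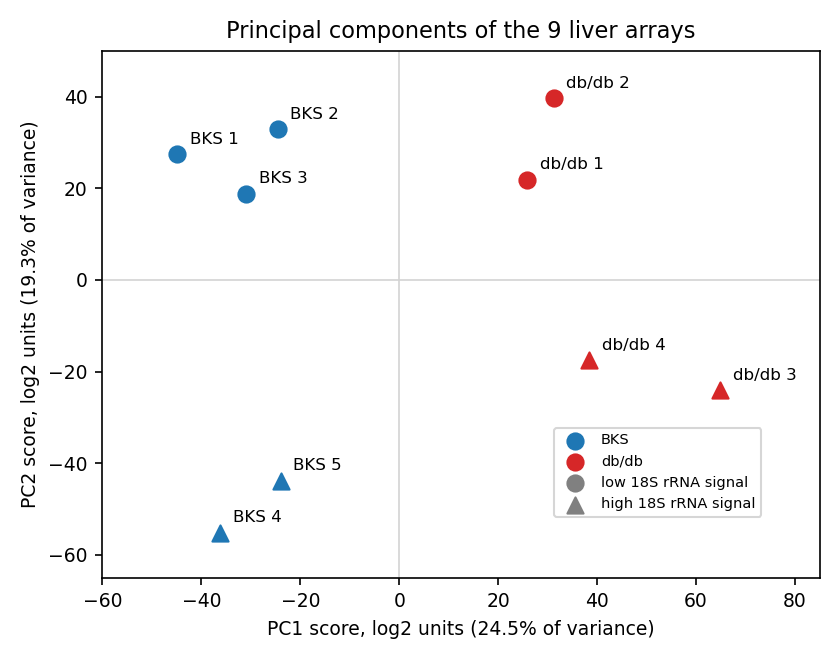
Scores of the 9 liver arrays on the first and second principal components (log2 units, with the percent of variance on each axis), coloured by genotype and shaped by the 18S rRNA signal. The genotypes lie on opposite sides of 0 on the first axis, with 24.5% of the variance, and the 4 arrays of high 18S signal lie below 0 on the second, with 19.3%.

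The study asks how peroxisomes and mitochondria are affected in db/db liver. Lepr itself, the mutated gene, was dim in liver on all 4 of its probe sets, and none passed the test (limma with Benjamini-Hochberg adjustment, adjusted p from 0.335 to 0.881). The db mutation alters the splicing of the receptor's message, so these levels do not check the genotype.

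Livers of db/db mice had more RNA of genes that female mouse liver normally expresses and of genes of fatty acid oxidation, and less of genes typical of male liver. The largest rises were those of Sult3a1, a sulfotransferase (184-fold, from 6.05 ± 2.15 to 13.58 ± 0.71 on the log2 scale, SD, n = 5 and 4), Cyp2b9, a cytochrome P450 (104-fold), and Cyp4a14, a fatty acid hydroxylase (59.2-fold). Acot3, Sult2a2, Cyp2b13 and Sult1e1 followed with 53.8-fold to 31.8-fold rises, then Cd36, which takes up fatty acids (25.8-fold), Mfsd2a, a lysophospholipid transporter (24.8-fold), and Slc22a27 (20.2-fold). The largest falls were those of Hsd3b5, a steroid-metabolising enzyme (363-fold lower, from 13.64 ± 0.48 to 5.13 ± 0.88), Moxd1 (150-fold) and Slco1a1, an organic anion transporter (65.9-fold). Scara5, a ferritin receptor (58.2-fold), Serpina4-ps1 (38.6-fold), Ugt2b38 (24.9-fold), Serpina12, which encodes vaspin (22.8-fold), Fabp5, a fatty acid binding protein (16.8-fold), complement C6 (11.8-fold) and Cdh1, which encodes E-cadherin (9.69-fold), completed the 10. Their adjusted p ran from 2.90e-08 for Cyp2b9 to 0.00541 for Sult2a2. These 20 genes were taken only from called genes whose groups do not overlap. That all their db/db arrays lay on 1 side of all BKS arrays was thus fixed in advance and is no separate support. Folds are on the log2(signal + 16) scale, and for genes dim in 1 group their size and order depend on the amount added: with 1 and 64 in its place the log2 fold change was -9.52 and -7.22 for Hsd3b5, -8.06 and -6.10 for Moxd1, -7.19 and -4.40 for Scara5 and 8.42 and 6.49 for Sult3a1. The other probe set of Scara5 stood at -0.17.

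Several of these folds also moved by over 1.5 times with 1 array left out, while their calls held. Sult3a1 stood at 8.47 on the log2 scale without BKS 3 (7.53 with all arrays), Cyp4a14 at 6.75 without BKS 2 and 5.25 without BKS 4 (5.89), Sult1e1 at 5.68 without BKS 5 (4.99), Cyp2b13 at 4.70 without db/db 3 (5.35) and Cd36 at 4.10 without BKS 4 (4.69). Sult2a2 stood at 6.24 without BKS 3, 4.49 without db/db 3 and 6.17 without db/db 4 (5.47). Among the falls, C6 stood at -2.89 without db/db 3 (-3.57), and Slco1a1 at -6.70, -6.89, -5.27 and -5.30 without db/db 1, 2, 3 and 4 (-6.04). Serpina4-ps1 stood at -7.45 without db/db 1 (-5.27). Each fit picked the brightest probe set anew, and that value came from another of the gene's 3 probe sets (-7.34 to -5.27 with all arrays). It therefore does not measure the weight of db/db 1.

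In all, 526 genes rose and 473 fell (limma, Benjamini-Hochberg adjusted p under 0.05), 440 and 407 of them by at least 1.5-fold. At an unadjusted p under 0.05 there were 3208 genes. Of the 999 called genes, 923 had groups that did not overlap. Over all genes the share was 9.15%, against 1.59% by chance. With the 18S split as a block 747 genes rose and 751 fell, including all 999, and the group means of all 999 differed in the same direction within both sets of arrays. For the 923 genes without overlap this direction was fixed in advance, since both sets hold both genotypes. It is thus no separate support. When each set was normalized and fitted alone, the low 18S arrays gave 207 and 202 genes and the high 18S arrays 245 and 232, and 4 and 3 of the 999 had the opposite sign. Without db/db 3 there were 308 and 281.

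Genes of peroxisomal fatty acid oxidation rose as a group, among them the acyl-CoA thioesterases Acot3 (53.8-fold) and Acot4 (9.12-fold), Abcd2, a transporter of very long chain acyl-CoA in the peroxisomal membrane (15.1-fold), and the enoyl-CoA isomerase Eci2 (1.93-fold). Of 25 measured members 11 rose and 2 fell (14 and 2 adjusted over the list alone). Those that fell were Nudt7, which cleaves coenzyme A in peroxisomes (log2 fold change -1.27, SE 0.14, adjusted p = 1.54e-04), and Crot, a carnitine octanoyltransferase (-0.50, SE 0.13, adjusted p = 0.0436). The median log2 fold change of the list was 0.48 (camera adjusted p = 6.85e-08, and adjusted p = 0.0190 with an estimated correlation). It was 0.49 with the 18S split as a block, 0.42 in the low and 0.39 in the high 18S arrays. Acot3 and Abcd2 also stand in the list of female-biased genes and Nudt7 in that of male-biased genes. The 4 probe sets of Abcd2 ran from 0.33 to 3.92 in log2 fold change, and 2 of them were called. The call of Crot was lost in 7 of 9 fits that left out 1 array (adjusted p up to 0.141), and its sign turned to 0.17 with the probe set of largest variance.

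Genes that build peroxisomes changed little. Of 13 measured peroxins 2 rose and 1 fell (3 and 1 adjusted over the list alone). Pex19, which brings membrane proteins to peroxisomes, rose by 0.64 on the log2 scale (SE 0.13, adjusted p = 0.00922), and Pex7, an import receptor, by 0.40 (SE 0.11, adjusted p = 0.0410). Pex6, an ATPase that recycles the import receptors, fell by 0.92 (SE 0.25, adjusted p = 0.0466). Pex5, the main import receptor, was at 0.69 and did not pass (SE 0.22, adjusted p = 0.101), with db/db 3 far above the other db/db arrays. The median of the list was 0.22 (camera adjusted p = 0.0280), with 0.21 under the block, 0.21 in the low and 0.24 in the high 18S arrays, and the call was lost with an estimated correlation (adjusted p = 0.118). It was also lost without db/db 3 (median 0.08, adjusted p = 0.0647) and without db/db 1 (0.21, adjusted p = 0.0602). The calls of Pex7 and Pex6 were lost in 8 and 7 of the 9 fits with 1 array left out. Pex6 stood at -0.28 without BKS 4, where another of its 5 probe sets (-0.92 to -0.07 with all arrays) was picked. Among 23 other peroxisomal proteins, Gstk1, a glutathione transferase (1.89-fold), and Hao2, a hydroxyacid oxidase (9.03-fold), rose and Hao1, the glycolate oxidase, fell (1.67-fold), with the same counts adjusted over the list alone. That list did not pass (median 0.13, camera adjusted p = 0.302), and the call of Hao2 was lost in 7 of the 9 fits (adjusted p up to 0.0975), with a log2 fold change of 3.80 without BKS 1 and 2.48 without db/db 3 (3.18 with all arrays).

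Genes of mitochondrial fatty acid oxidation rose as a group: 12 of 19 measured members rose and none fell (17 and 0 adjusted over the list alone), and all 19 had a positive change. Examples were Eci1, an enoyl-CoA isomerase (1.76-fold, adjusted p = 0.00268), the carnitine transporter Slc22a5 (2.00-fold, adjusted p = 0.00362), Cpt2, the inner carnitine palmitoyltransferase (1.55-fold, adjusted p = 0.00412), and Acadm, which oxidises medium chain fatty acids (1.42-fold, adjusted p = 0.00571). The median log2 fold change was 0.50 (camera adjusted p = 2.26e-14, and adjusted p = 0.0138 with an estimated correlation), with 0.46 under the block and 0.48 in both sets of arrays. The other probe set of Cpt2 stood at a log2 fold change of 0.00.

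Few subunits of oxidative phosphorylation passed the test. Of 72 measured subunits 3 rose and none fell (2 and 0 adjusted over the list alone): Sdhb of complex II (1.38-fold), Uqcrfs1 of complex III (1.31-fold) and Ndufb7 of complex I (1.42-fold). The median was 0.09 (camera adjusted p = 0.00453), with 0.07 under the block, 0.10 in the low and 0.05 in the high 18S arrays. The call was lost with an estimated correlation (adjusted p = 0.289) and, narrowly, with fry (adjusted p = 0.0502). The median fell to 0.05 without BKS 1 (adjusted p = 0.0285) and to 0.06 without db/db 3 (adjusted p = 0.0136), and the calls of Uqcrfs1 and Ndufb7 were lost in 6 and 7 of the 9 fits with 1 array left out.

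Of 21 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase 6 rose and none fell, over all genes and over the list alone (median 0.28, camera adjusted p = 8.90e-06, and adjusted p = 0.0199 with an estimated correlation, 0.26 and 0.22 in the low and high 18S arrays). Pdk1, which inhibits pyruvate dehydrogenase (1.73-fold, adjusted p = 0.0101), and Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase (1.74-fold, adjusted p = 0.0130), were among them. Idh2 stood at -0.57 with its probe set of largest variance and missed the threshold without db/db 3 (adjusted p = 0.0542). Mitochondrial biogenesis and dynamics did not pass as a list (22 genes, median 0.07, camera adjusted p = 0.759): Mfn2, which fuses mitochondria, rose (1.43-fold) and Mff, which helps divide them, fell (1.60-fold), with 3 and 2 genes adjusted over the list alone. Both calls were lost in 7 of the 9 fits with 1 array left out. Mfn2 stood at -0.03 with its probe set of largest variance, and the probe sets of Mff ran from -0.68 to 0.14. None of 4 genes of ketone body synthesis passed over all genes (limma, 3 at an unadjusted p under 0.05, 2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.201). With the 18S split as a block 1 of them rose and 1 fell. Bdh1, a ketone body dehydrogenase, was at 0.53 (SE 0.15, adjusted p = 0.0614).

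**Figure D2:**
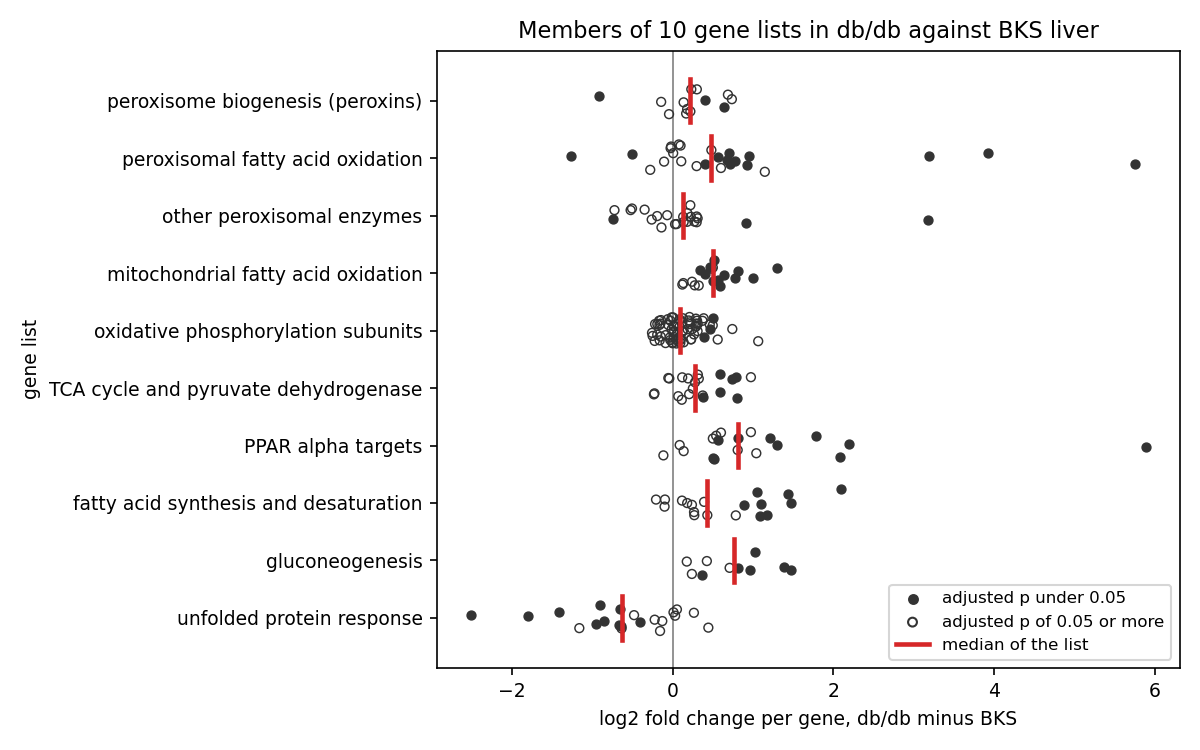
Log2 fold change, db/db minus BKS, of each measured member (points, filled where the adjusted p is under 0.05) and the median (red bar) for 10 gene lists. All 19 members of mitochondrial fatty acid oxidation lie above 0, the 72 subunits of oxidative phosphorylation lie around a median of 0.09, and the unfolded protein response lies around -0.63.

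Targets of PPAR alpha, a nuclear receptor that senses fatty acids, rose together: 10 of 19 rose and none fell (16 and 0 adjusted over the list alone). Besides Cyp4a14, the retinol saturase Retsat rose 2.31-fold (adjusted p = 2.17e-04) and the thioesterase Acot1 4.59-fold (adjusted p = 6.04e-04). The median was 0.81 (camera adjusted p = 2.43e-14, and adjusted p = 0.0199 with an estimated correlation), with 0.51 in the low and 0.81 in the high 18S arrays. This list shares 4 genes with mitochondrial and 1 with peroxisomal fatty acid oxidation.

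Genes of fatty acid synthesis also rose, 8 of 19 with none lower (9 and 0 adjusted over the list alone), among them the elongase Elovl6 (4.28-fold, adjusted p = 2.64e-04) and Pklr, liver pyruvate kinase (2.79-fold, adjusted p = 5.45e-04). Scd1, a desaturase with a bright signal in both groups, was at -0.10 (SE 0.21, adjusted p = 0.867). The median was 0.43 (camera adjusted p = 5.93e-08), 0.40 in the low and 0.91 in the high 18S arrays and 0.29 without BKS 4, and the call was lost with an estimated correlation (adjusted p = 0.151). In triglyceride synthesis, storage and secretion 7 of 29 genes rose and 1 fell (15 and 2 adjusted over the list alone). Cd36 and Apoa4, an apolipoprotein of triglyceride-rich particles (4.91-fold, adjusted p = 1.01e-05), rose, and Lpl, lipoprotein lipase, fell (2.23-fold, adjusted p = 0.0209, and 0.0674 without db/db 3 and 0.0547 without db/db 4). The median of that list was 0.35 (camera adjusted p = 5.93e-08, and adjusted p = 0.0138 with an estimated correlation), with 0.33 in the low and 0.56 in the high 18S arrays. It shares 2 genes with the list of PPAR alpha targets.

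Cholesterol synthesis gained only 1 called gene of 20 (2 adjusted over the list alone), Mvd, mevalonate diphosphate decarboxylase (1.64-fold, adjusted p = 0.0364, lost in 7 of the 9 fits). The median was 0.21 (camera adjusted p = 0.00524), with 0.07 in the low and 0.27 in the high 18S arrays, and the call was lost with an estimated correlation (adjusted p = 0.310) and without BKS 4 (adjusted p = 0.141). Of 20 genes of bile acid synthesis and transport 8 rose and 3 fell (9 and 4 adjusted over the list alone). The transporters Abcc4 (15.4-fold) and Abcb4 (1.73-fold) rose, and Cyp7b1, an oxysterol hydroxylase, and Slco1a1 fell (9.55-fold and 65.9-fold). Cyp7b1 and Slco1a1 also stand in the list of male-biased genes. The 3 probe sets of Cyp7b1 ran from -3.80 to -0.33 in log2 fold change, and 2 of them were called. The median of this list was 0.23 (camera adjusted p = 0.0332), with 0.20 in the low and 0.27 in the high 18S arrays, and the call was lost with an estimated correlation (adjusted p = 0.118) and without BKS 4, db/db 1 or db/db 2 (adjusted p from 0.0581 to 0.0720).

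Genes of glucose production rose: 6 of 10 in gluconeogenesis with none lower (8 and 0 adjusted over the list alone). Slc37a4, which carries glucose 6-phosphate to the enzyme that frees glucose, rose 2.03-fold (adjusted p = 9.26e-05) and the aminotransferase Got1 2.79-fold (adjusted p = 1.67e-04). The median was 0.76 (camera adjusted p = 2.78e-09, and adjusted p = 0.00734 with an estimated correlation), with 0.76 in the low and 0.72 in the high 18S arrays. Glycolysis and fructose metabolism, which shares Pklr with fatty acid synthesis, had 5 of 15 genes higher and none lower (7 and 0 adjusted over the list alone), with the triokinase Tkfc at 2.72-fold. Its median was 0.37 (camera adjusted p = 9.29e-06, and adjusted p = 0.0138 with an estimated correlation), with 0.19 in the low and 0.42 in the high 18S arrays. Insulin signalling and glycogen moved in both directions and did not pass as a list (21 genes, 2 higher and 3 lower by both adjustments, camera adjusted p = 0.546). The glycogen enzymes Gbe1 (2.01-fold) and Gys2 (1.41-fold, lost in 7 of the 9 fits) rose, while Igfbp2, which binds insulin-like growth factors (3.34-fold), and Socs2, an inhibitor of cytokine receptor signalling (6.36-fold), fell. Socs2 stood at -1.83 on the log2 scale without BKS 1 (-2.67 with all arrays), where another of its 6 probe sets (-2.67 to -0.44 with all arrays) was picked. In the urea cycle and amino acid catabolism 4 of 24 genes rose and none fell (7 and 0 adjusted over the list alone), among them Asl, argininosuccinate lyase (1.69-fold), and Bckdhb of branched chain keto acid breakdown (1.57-fold). The median was 0.19 (camera adjusted p = 8.90e-06, and adjusted p = 0.0316 with an estimated correlation, lost with the 18S block as well, adjusted p = 0.0622 with an estimated correlation), with 0.20 in the low and 0.18 in the high 18S arrays.

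Genes that differ between the sexes in mouse liver moved furthest of the lists. Of 17 female-biased genes 12 rose and none fell (14 and 0 adjusted over the list alone), with a median of 3.18 (camera adjusted p = 1.33e-20, and adjusted p = 0.00734 with an estimated correlation). Besides Sult3a1 and Cyp2b9, Cyp17a1, a steroid hydroxylase, rose 12.1-fold (adjusted p = 1.51e-07). Of 14 male-biased genes 10 fell and none rose (0 and 11 adjusted over the list alone), with a median of -1.97 (camera adjusted p = 3.39e-18, and adjusted p = 0.0380 with an estimated correlation). With the 18S split as a block the last of these calls was lost (adjusted p = 0.0622 with an estimated correlation). Within the low and the high 18S arrays the medians were 2.19 and 3.93 for the female-biased list and -1.38 and -2.71 for the male-biased list.

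**Figure D3:**
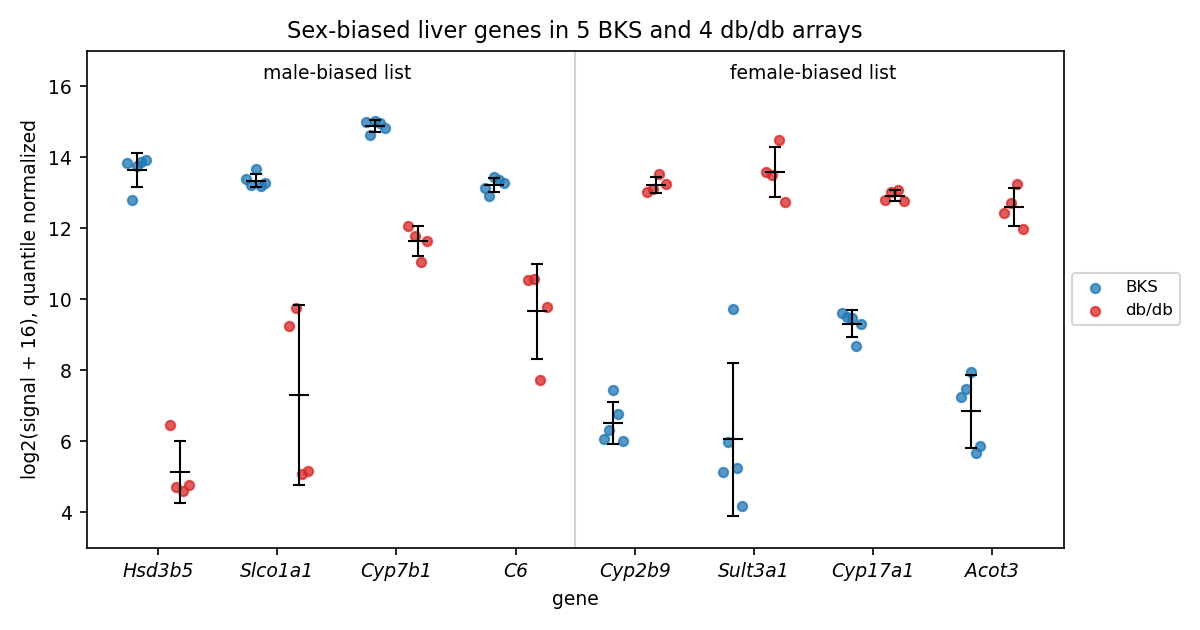
Level of 4 male-biased and 4 female-biased liver genes in each of the 5 BKS and 4 db/db arrays (points), with the mean and SD (bars), as log2(signal + 16) after quantile normalization. Every db/db array lies below every BKS array for the male-biased genes shown and above for the female-biased genes shown. All but Cyp7b1 and Cyp17a1 are among the largest changes, which were picked from genes without overlap.

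Genes of cytochrome P450 and drug metabolism split, with 9 of 24 higher and 5 lower (12 and 5 adjusted over the list alone). Ces1g, a carboxylesterase (2.13-fold), and Cyp2b10, a target of the xenobiotic receptor CAR (10.7-fold), rose, and Cyp2c70, which makes muricholic acids (3.35-fold), and Gstp1, a glutathione transferase (1.65-fold), fell. The median was 0.31 (camera adjusted p = 0.00477, and adjusted p = 0.0453 with an estimated correlation, lost with the 18S block as well, adjusted p = 0.0564 with an estimated correlation), with 0.20 in the low and 0.42 in the high 18S arrays. Among 19 antioxidant genes 3 rose and 1 fell (7 and 1 adjusted over the list alone). The quinone reductase Nqo1 rose 3.03-fold (adjusted p = 0.00873). The peroxiredoxins Prdx3 of mitochondria and Prdx4 of the endoplasmic reticulum rose 1.35-fold and fell 1.43-fold, calls that were lost in 6 and 5 of the 9 fits with 1 array left out. The 4 probe sets of Prdx4 ran from -1.17 to 0.69. The median of this list was 0.29 (camera adjusted p = 0.0228), with 0.23 in the low and 0.03 in the high 18S arrays, and the call was lost with an estimated correlation (adjusted p = 0.0821) and without db/db 4 (median 0.11, adjusted p = 0.0602). Without BKS 1 the median was 0.07.

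The unfolded protein response fell: 10 of 21 genes were lower and none higher (0 and 13 adjusted over the list alone). Herpud1 (0.27) and Trib3 (0.45) were among 5 members with a positive change and did not pass. Of the 2 probe sets of Herpud1 (0.27 and 0.98), 1 was called higher when each probe set was tested on its own. Xbp1, a transcription factor of this response, fell 1.93-fold (adjusted p = 1.83e-04), and Sdf2l1, a protein of the endoplasmic reticulum, fell 5.69-fold (adjusted p = 4.52e-04). The median was -0.63 (camera adjusted p = 3.93e-08, and adjusted p = 0.0442 with an estimated correlation), with -0.44 in the low and -0.65 in the high 18S arrays. With the 18S split as a block the call with an estimated correlation was lost (adjusted p = 0.0537 with an estimated correlation). Of 20 acute phase proteins 5 fell and none rose (0 and 9 adjusted over the list alone), among them the serum amyloids Saa4 (2.76-fold) and Saa3 (2.17-fold). That median was -0.29 (camera adjusted p = 1.05e-06), with -0.42 in the low and -0.14 in the high 18S arrays, and the call was lost with an estimated correlation (adjusted p = 0.238). No gene passed among 19 of fibrosis and matrix and 18 inflammatory cytokines and chemokines by either adjustment (limma, 5 and 3 at an unadjusted p under 0.05, camera adjusted p = 0.896 and 0.982). With the 18S split as a block 1 of the cytokines and chemokines fell. Of the 3 probe sets of Cxcl1 (-1.95 to -0.32), 1 was called lower when each probe set was tested on its own. For fibrosis and matrix the median was 0.12 while camera pointed down.

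Few markers of cell types passed the test. None of 11 hepatocyte markers passed (limma, 3 at an unadjusted p under 0.05, median 0.03, mean -0.03, camera adjusted p = 0.891). Among 17 macrophage and Kupffer cell markers none passed either (5 at an unadjusted p under 0.05), though 2 fell with the 18S split as a block. Their median was -0.25 (camera adjusted p = 0.0279), -0.51 in the low and -0.08 in the high 18S arrays, a call lost with an estimated correlation (adjusted p = 0.529) and without BKS 1, BKS 2, BKS 3 or db/db 3 (adjusted p from 0.0827 to 0.391). The median was -0.11 without BKS 2, -0.52 without BKS 4 or BKS 5 and -0.48 without db/db 1. The other lists did not pass: stellate cells (camera adjusted p = 0.106), endothelial cells (0.0743, and 0.0152 with the 18S split as a block, a call lost there at adjusted p = 0.307 with an estimated correlation), cholangiocytes (0.189), T and NK cells (0.408), B and plasma cells (0.136), neutrophils (0.944), erythroid cells (0.658), adipocytes (0.175), pancreatic acinar cells (0.587) and skeletal muscle (0.982). Of these, fry called B and plasma cells (adjusted p = 0.0367) and adipocytes (adjusted p = 0.0478). Single markers did: Ecm1 of stellate cells (1.92-fold) and Nrg4 (4.32-fold) and Fabp4 (2.56-fold) of adipocytes rose, while Alas2 of erythroid cells (2.30-fold) and Cela1 of acinar cells (2.73-fold) fell. The calls of Ecm1 and Fabp4 were lost in 6 of the 9 fits with 1 array left out, and the 4 probe sets of Fabp4 ran from -0.35 to 1.36.

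Of 43 lists tested, camera called 22, 17 with a median above 0 and 5 below. All 22 kept their call with the 18S split as a block and the sign of their median within both sets of arrays. With an estimated correlation 13 held, and 8 of these held with the block as well. The 5 that did not were the lists of male-biased genes, cytochrome P450, the unfolded protein response, the urea cycle and the clock.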

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

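The tests of the 18S split below were chosen after the split was seen. Of 286 groups of 4 or 5 values tested with Dixon's ratio, the gap of the extreme array to its neighbour over the range of the group, 15 lay past the 95% limit. Chance flags about 1 in 20 groups. Among the BKS arrays, BKS 2 was far below the others for Hsd3b5 (ratio 0.836), Cdh1 (0.788) and Nudt7 (0.747) and for the mean of the tricarboxylic acid cycle list (0.842). BKS 4 was far below the others for Cd36 (0.734), and BKS 3 for the mean of the glycolysis list (0.733). BKS 1 was far above for Fabp4 (0.717) and Cyp1a2 (0.778). Among the db/db arrays, db/db 3 was far above the others for Slc22a27 (0.951) and Pex5 (0.900) and far below for Etnppl (0.961) and for the mean of the immediate-early list (0.896). The array db/db 1 was far above for Hsd3b5 (0.919), db/db 2 far below for Sdf2l1 (0.894) and db/db 4 far below for Fabp4 (0.904). Among 10092 probe sets without a single gene name, left out of the gene table, 44 were higher and 23 lower in db/db (limma, Benjamini-Hochberg adjusted p under 0.05).

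The arrays BKS 4, BKS 5, db/db 3 and db/db 4 had a high 18S ribosomal RNA signal and stood apart on the second principal component. Genotype is argued against, since 2 of these 4 arrays were db/db, and so is a plain difference of scale, since the split still held 88.2% of that component after quantile normalization. The lowest signal of the added hybridisation control CreX in these 4 arrays was 1.19 times the highest in the other 5 (exact two-sided permutation p = 0.0159), and the actin 3'/5' ratio was higher (exact two-sided permutation p = 0.0238). A candidate explanation is a different labelling round on these arrays. Less labelled liver RNA stays a candidate for the CreX signal, which was 1.49 log2 units higher. The 18S signal differed far more (1873 to 19771 against 22.2 to 43.5), which argues against less labelled RNA as the whole explanation. The labels give no batch, and no biological explanation other than genotype was tested.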

How the results depend on the processing

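The settings without quantile normalization, with the 18S block and within each 18S set were chosen after the data were seen. Mitochondrial and peroxisomal fatty acid oxidation kept their call and sign under the 28 alternatives that changed 1 choice or averaged probe sets under the 18S block (medians 0.44 to 0.58 and 0.31 to 0.60, highest adjusted p 0.0138 and 0.0190). With an estimated correlation and the 18S block together their adjusted p was 0.0255 and 0.0467. Peroxins kept theirs under 22 and oxidative phosphorylation under 24 of 28 (adjusted p from 0.00138 to 0.118 and from 0.00159 to 0.289). Peroxins missed the threshold with an estimated correlation (median 0.22, adjusted p = 0.118), above the 50th percentile of signal (0.22, adjusted p = 0.0671), without a trend (0.22, adjusted p = 0.0554) and in the high 18S arrays normalized and fitted alone (0.25, adjusted p = 0.0722). Oxidative phosphorylation missed it with an estimated correlation (0.0874, adjusted p = 0.289), fry (0.0874, adjusted p = 0.0502), the probe set of largest variance (0.10, adjusted p = 0.0697) and in the high 18S arrays alone (0.0510, adjusted p = 0.143). Against 526 higher and 473 lower genes, the numbers called were 323 and 212 with centring on the median, 254 and 212 without a trend, 167 and 117 with Welch's test per gene, 406 and 273 with averaged probe sets and 370 and 260 with the probe set of largest variance. The 18S block gave 747 and 751, the low 18S arrays 207 and 202 and the high 18S arrays 245 and 232, with fewer arrays in the last cases. Values without quantile normalization gave 468 and 450. With 1 array left out, 308 to 521 genes were higher and 281 to 438 lower, and the peroxin median ran from 0.0839 to 0.274. The replicate numbers as a block, though they did not pair the samples, gave 596 and 550. The share of higher genes ran from 49.3% to 60.4%. Of the 999 called genes, 94 had the opposite sign with the probe set of largest variance and 12 with averaged probe sets. With the probe set of largest variance Crot stood at 0.17, Idh2 at -0.57 and Mfn2 at -0.0317, because that rule picks another probe set. Other causes were not tested. Planned quantile normalization was already the first choice and so was not run again, and lists were not computed under Welch's test or robust eBayes. Without detection calls, signal over background was not measured.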

Other observations

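The tests of clock phase, of the 18S split, of gene families, of the sex-biased members of the peroxisomal list and of the difference between the peroxisomal and mitochondrial lists were chosen after the results were seen. Genes of the circadian clock and its output rose in part: 5 of 19 rose and none fell (9 and 2 adjusted over the list alone), among them Ciart, a repressor within the clock (7.82-fold, adjusted p = 4.02e-04), and Nampt, an enzyme of NAD synthesis (1.90-fold, adjusted p = 7.89e-04). The median log2 fold change was 0.81 (camera adjusted p = 7.19e-04, and adjusted p = 0.0255 with an estimated correlation, lost with the 18S block as well, adjusted p = 0.0560 with an estimated correlation), with 0.84 in the low and 0.29 in the high 18S arrays. Heat shock proteins were lower, with 2 of 10 called, Hspb1 (5.79-fold) and Hsp90aa1 (1.89-fold), and 5 adjusted over the list alone. The 5 probe sets of Hsp90aa1 ran from -0.92 to 0.51. Their median was -0.62 (camera adjusted p = 5.20e-04), -0.25 in the low and -0.87 in the high 18S arrays, and the call was lost with an estimated correlation (adjusted p = 0.238). Of 17 immediate-early genes 2 fell and none rose by both adjustments, Egr1 (8.82-fold) and Junb (2.23-fold, lost in 8 of the 9 fits), and the list did not pass (camera adjusted p = 0.190).

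Genes of liver zones did not move as lists. In the pericentral list of 10, Oat (2.02-fold) and Rhbg, an ammonium transporter (4.51-fold), rose and Cyp1a2 fell (1.57-fold, lost in 6 of the 9 fits), with the same counts adjusted over the list alone (camera adjusted p = 0.300). In the periportal list of 10, Etnppl rose (2.49-fold) and Cdh1 fell (9.69-fold), again with the same counts (camera adjusted p = 0.922, median 0.04, mean -0.16). None of 18 cell cycle genes passed by either adjustment (limma, 3 at an unadjusted p under 0.05, camera adjusted p = 0.982, median -0.23, mean 0.00). Among 243 gene families with at least 10 measured members, the acyl-CoA thioesterases, which free fatty acids from coenzyme A, held a call with an estimated correlation: 7 of 12 rose and none fell (median 0.90, adjusted p = 2.73e-09, and adjusted p = 0.0447 with an estimated correlation). The median was 0.95 with centring on the median and 0.88 without quantile normalization.

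Of 100 splits of the 9 arrays drawn, the real one included, only the real split gave as many called genes. It gave 526 higher genes (the highest other 92) and 473 lower genes (the highest other 168). Such counts are thus unlikely by chance, though 1 of 100 is the smallest share that these splits can give. The highest other split was that along the 18S signal. In this permutation of the arrays the camera p of mitochondrial fatty acid oxidation was also strongest in the real split (1.58e-15, 1 split as strong, the strongest other 6.04e-13). For peroxisomal fatty acid oxidation only the real split was as strong (camera p 1.43e-08). Another split came close (camera p 1.85e-08), so the real groups barely stood out there. For peroxins 2 of the 100 splits were as strong (real camera p 0.0137 by permutation of the arrays, the strongest other 0.00684), so another split gave a smaller p than the real one, and the call was also lost with an estimated correlation (adjusted p = 0.118). For oxidative phosphorylation chance cannot be excluded (6 splits, camera p 0.00169, the strongest other 7.34e-04). The 18S split itself gave camera p from 0.111 to 0.818 for these lists.

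Sex-biased genes moved toward the female pattern in db/db liver. Female animals among the db/db samples are argued against, since the 3 measured Y-linked genes had a median log2 fold change of -0.24, at gene means on the log2 scale from 8.42 to 10.79 in BKS and from 7.90 to 10.54 in db/db. The medians of the arrays were 6.38 to 6.99 before quantile normalization. The 18S split is argued against too: the gap between the medians of the female-biased and male-biased lists was 3.57 in the low and 6.64 in the high 18S arrays. Weaker growth hormone signalling through STAT5, which maintains the male pattern, may contribute and stays open, since Igf1, Igfals and Cish had a median of -0.54 and 1 of 3, Cish, passed.

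Clock genes that peak with Dbp were higher in db/db (11 of 11) and those that peak with Arntl lower (5 of 5), with 4 and 0 past the threshold over all genes. The difference between the mean levels of these sets per array was 2.01 log2 units larger in db/db (exact two-sided permutation p = 0.0317). The median log2 fold change over all arrays was 1.21 for the Dbp set and -0.56 for the Arntl set. The 18S split is argued against, since the difference between these medians was 2.34 in the low and 1.43 in the high 18S arrays. A candidate explanation is a different clock phase at collection, from another collection hour or from altered feeding rhythm in db/db mice. The hour of collection is not given in the sources used here, so these cannot be told apart.

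The hypothesis that sex-biased members carry the rise of the peroxisomal fatty acid oxidation list was not borne out: without Acot3, Abcd2 and Nudt7 the other 22 genes had a median of 0.44 (camera p = 7.18e-08, and p = 0.00327 with an estimated correlation). The hypothesis that the peroxisomal list rose more than the mitochondrial list was tested on the difference of their mean log2 levels per array. That difference was 0.24 larger in db/db (exact two-sided permutation p = 0.00794, the smallest possible). Without the sex-biased members it was -0.03 (exact permutation p = 0.492). The median log2 fold changes of the full lists did not show a larger peroxisomal rise (0.48 peroxisomal, 0.50 mitochondrial). The hypothesis that the fall of the unfolded protein response extends to other secretory pathway genes stays open: 65 such genes had a median of -0.21, 6 fell and 1 rose (camera p = 1.28e-04, and p = 0.0672 with an estimated correlation).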
